A study of Mus musculus with 65 samples.

How the data were processed

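The series holds 65 single neurons from the nucleus of the solitary tract (NTS), a brainstem nucleus that receives visceral signals, of male mice of mixed strain. The mice carried an Hsd11b2-Cre driver and the Ai9 reporter, which makes the red protein tdTomato wherever Cre has acted, and red cells were picked by hand from a suspension made with papain, per the labels. The labels' protocols name Arc-ME as the digested tissue, whereas the tissue label of every sample is the NTS, and the tissue label was followed. Libraries of polyA RNA were made from each frozen cell with Smart-Seq2, a method for full-length cDNA from a single cell, and Nextera XT. The diet label puts 33 neurons in the standard chow group and 32 in the low-sodium group.

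Per the submitters' processing notes, the tools named are bcl2fastq, HISAT2 2.0.5, Picard 2.5.0, SAMtools 0.1.19 and featureCounts 1.4.6, with the builds mm10 and GRCm38. Their settings, the gene annotation, any filter on cells and the total by which reads were scaled are not given in the sources used here. The values the authors deposited are log2(CPM + 1) per gene and cell, where CPM are scaled read counts. The table has 12015 lines of genes, each above 0 in at least 5 cells. Of these, 121 lines share 60 names and 19 carry serial numbers in place of names. Both kinds stayed in totals per cell and were left out of everything else, which left 11875 genes.

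CPM were computed from the deposited log2 values by undoing the log2 and subtracting 1. In each cell, 100% of the CPM up to 20 times the smallest step were whole multiples of that step within 0.1 steps, so a step was taken as 1 read. Reads over the listed genes ran from 50078 to 5319462 per cell, with a median of 651333. A single read stood for 0.16 to 16.1 CPM, with a median of 1.58 CPM, and a transcript under that level can be missed in that cell. The CPM of a cell summed to 754874 to 1147326 in 56 cells and to 1393471 to 2170050 in 9 cells, all from the low-sodium group. A limit of 1200000, set after the values were seen, separates them. Sums above the total that CPM stands for, found in 17 cells (5 chow and 12 low-sodium), cannot come from scaling to all reads of the same cell, so another total was used, which is not known, and levels in the 9 cells depend on that scale. The libraries carry no molecular identifiers in the sources used here. All intervals cover counting error over cells only, and not the spread between animals.

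The labels name no animal, so each diet is 1 sample and cells are not replicates of it. No test between diets was run, and no p-value, standard error or number of changed genes is given. Values are means with the SD over cells, which is the spread between cells. A diet difference is the mean log2(CPM + 1) of low-sodium cells minus that of chow cells. The pseudocount of 1 CPM shrinks differences between low values, and cells at 0 enter the mean. A difference is therefore not the fold of mean CPM, and can lie above or below it or have the other sign. The median over the genes that enter the random lists was -0.12, and 0.16 as the log2 ratio of mean CPM plus 1. A transcript was taken as detected above 0, and shares of cells have exact (Clopper-Pearson) 95% binomial intervals.

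A panel of identity genes, the other gene lists (21 with the panel) and 10 lists of cell type markers were fixed before the data were examined, as were the comparisons and the rule for naming genes. A list was described by the median difference over its members with a mean log2(CPM + 1) of at least 1, and by the percentile of that median among 10000 random lists of the same size matched on mean level in 20 bins, as a description of these libraries. A list was called apart outside the percentiles 2.5 to 97.5. Genes of a list vary together from cell to cell, so the percentile is not a test. The naming rule took the panel, the 12 highest and 12 lowest differences among genes above 0 in at least 16 cells (leaving out predicted and unnamed models), up to 4 members of each list by size of difference, and up to 5 abundant members of the transmitter, neuropeptide, receptor and channel lists with family members set against them. Single members of the marker lists, and Th and Chat, fall outside this rule and were chosen after their values were seen. Some genes that the rule took are not reported here. Hspa1a with Hspa1b, and ribosomal protein genes with their many processed copies, share near-identical sequence, so their levels are uncertain.

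Other settings chosen beforehand were pseudocounts of 10 and 0.1 CPM, size factors by the median of ratios over genes above 0 in at least 90% of cells, CPM without the 20 highest genes, every cell thinned to 50000 reads, the log2 ratio of mean CPM plus 1, the median over cells, no limit or a limit of 3 on the mean of list members, the mean over members, detection at 1 or 10 CPM, other limits for markers, and leaving out single cells in turn, cells with fewer than 6473 genes (7 cells) or cells in which at least 3 markers of a non-neuronal list exceeded 10 CPM (24 cells). Those added after the values were seen were leaving out the 9 cells with high CPM sums, rescaling each cell to the same total, matching random lists on transcript length too (10 level bins with 5 length bins), and dropping Mt1, Mt2 and Ndrg2 from the corticosteroid list. Transcript length, GC content and gene positions came from GENCODE M21 (GRCm38), in which 94.0% of the genes used had a transcript under the same symbol.

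The procedure was tested on simulated cells in the low-sodium minus chow comparison, with 12015 genes of which 200 had planted differences. Planted differences of 1 and 2 came back with medians of 1.03 and 1.94, and those of -1 and -2 with medians of -1.01 and -1.93. Of 100 random lists of 20 unchanged genes, 8 were called apart. In the simulated cells each gene varied on its own, and no cells had high CPM sums. Genes of a real list vary together, so this number does not give the rate of such calls for the real lists. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.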

Results

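RNA was sequenced from 65 single HSD2 neurons, the neurons of the NTS that make the enzyme 11-beta-hydroxysteroid dehydrogenase type 2 and so can sense aldosterone, the adrenal hormone released when sodium is short. The neurons came from mice on standard chow (33 cells) or on a low-sodium diet (32 cells). Chow cells had 50078 to 3244893 reads in the listed genes (median 602351) and a median of 8246 detected genes (5717 to 11467). Low-sodium cells had 50540 to 5319462 reads (median 694430) and a median of 8146.5 detected genes (4700 to 11193). Pan-neuronal markers exceeded 10 CPM for at least 3 genes in all 65 cells. Animals are not named in the labels, so the diets have no replicates, and every SD is the spread over cells. In 9 low-sodium cells the CPM summed to 1393471 to 2170050 over the listed genes, against 754874 to 1147326 in the other 56 cells, and list medians, and the differences of some single genes, are also given without these cells. Other diet values are over all cells. Without the 9 cells the low-sodium group had a median of 1088899 reads, against 602351 in chow. Values without the 9 cells were not also thinned to the same depth.

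**Figure D1:**
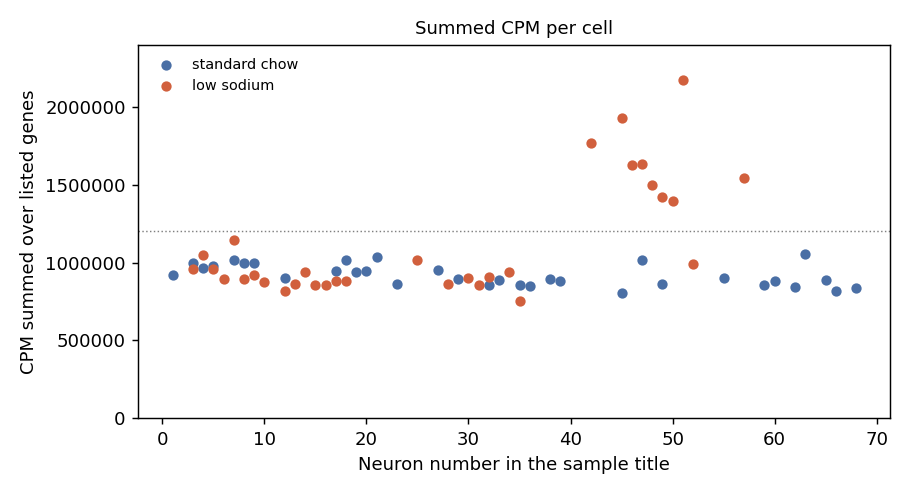
Each point is the CPM of 1 cell summed over the listed genes against the neuron number in the sample title, with a dotted line at the limit used to separate the 9 cells with high sums. Those 9 are low-sodium cells with numbers from 42 to 57, and no chow cell lies above the line.

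The first question was which steroid, angiotensin and transmitter genes the neurons express. Transcripts of Hsd11b2, which inactivates glucocorticoids and leaves the mineralocorticoid receptor free for aldosterone, were found in all 65 cells (interval 94.5% to 100%) at a mean log2(CPM + 1) of 8.87 ± 1.14. The mineralocorticoid receptor gene Nr3c2 was found in 62 cells (95.4%, 87.1% to 99.0%) at 5.96 ± 2.02, and the angiotensin II receptor gene Agtr1a in 63 cells (96.9%, 89.3% to 99.6%) at 7.07 ± 1.95. Slc17a6, the vesicular glutamate transporter VGLUT2, was found in all 65 cells at 8.86 ± 0.87. The neuropeptide gene Cartpt was found in 61 cells (93.8%, 85.0% to 98.3%) at 7.29 ± 2.68. The glucocorticoid receptor gene Nr3c1 was found in 43 cells (66.2%, 53.4% to 77.4%) at 3.08 ± 2.57. Lmx1b, a transcription factor, was found in 15 cells (23.1%, 13.5% to 35.2%), and H6pd, which supplies the cofactor of the related enzyme Hsd11b1, in 14 cells (21.5%, 12.3% to 33.5%). Thinning every cell to 50000 reads left the share with Nr3c1 at 46.2%, with H6pd at 10.8% and with Lmx1b at 9.23%, so those shares depend on depth.

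Most cells held transcripts of both receptor genes, Nr3c2 and Agtr1a. Nr3c2 and Hsd11b2 were both found in 62 of 65 cells (95.4%, 87.1% to 99.0%), Hsd11b2 and Agtr1a in 63 cells (96.9%, 89.3% to 99.6%), and Nr3c2 and Agtr1a in 61 cells (93.8%, 85.0% to 98.3%). Without the 7 cells with fewer than 6473 genes, each of these shares was 100%. The cells were picked by a reporter driven by Hsd11b2-Cre, and all 65 held Hsd11b2. Its shares with Nr3c2 and with Agtr1a therefore only repeat the shares of those genes alone. Slc17a6 shared a cell with Gad1 or Gad2, which encode the GABA-making enzymes, in 18 cells (27.7%, 17.3% to 40.2%), and in 16.9% of cells at 10 CPM or more. Gad1 was found in 10 of 33 chow cells (30.3%, 15.6% to 48.7%) and 2 of 32 low-sodium cells (6.25%, 0.766% to 20.8%), Gad2 in 7 chow and 6 low-sodium cells, and the mean of Gad1 and Gad2 was 1.41 ± 2.49 in chow and 0.43 ± 1.39 in low sodium. The highest such means were in chow neurons 55 (8.48), 59 (8.26) and 20 (7.10) and low-sodium neuron 9 (7.23). All of these cells carried non-neuronal markers, whereas the next, chow neuron 65 (5.30), did not. RNA of other cells as the source of Gad1 and Gad2 was not tested. On GRCm38 the protein-coding genes lie on chromosome 8 (Hsd11b2, 105518755 to 105523988, and Nr3c2, 76899442 to 77245012), chromosome 13 (Agtr1a, 30336441 to 30382867, and Cartpt, 99898489 to 99901091) and chromosome 7 (Slc17a6, 51622006 to 51671119), and of these only Cartpt is on the minus strand.

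**Figure D2:**
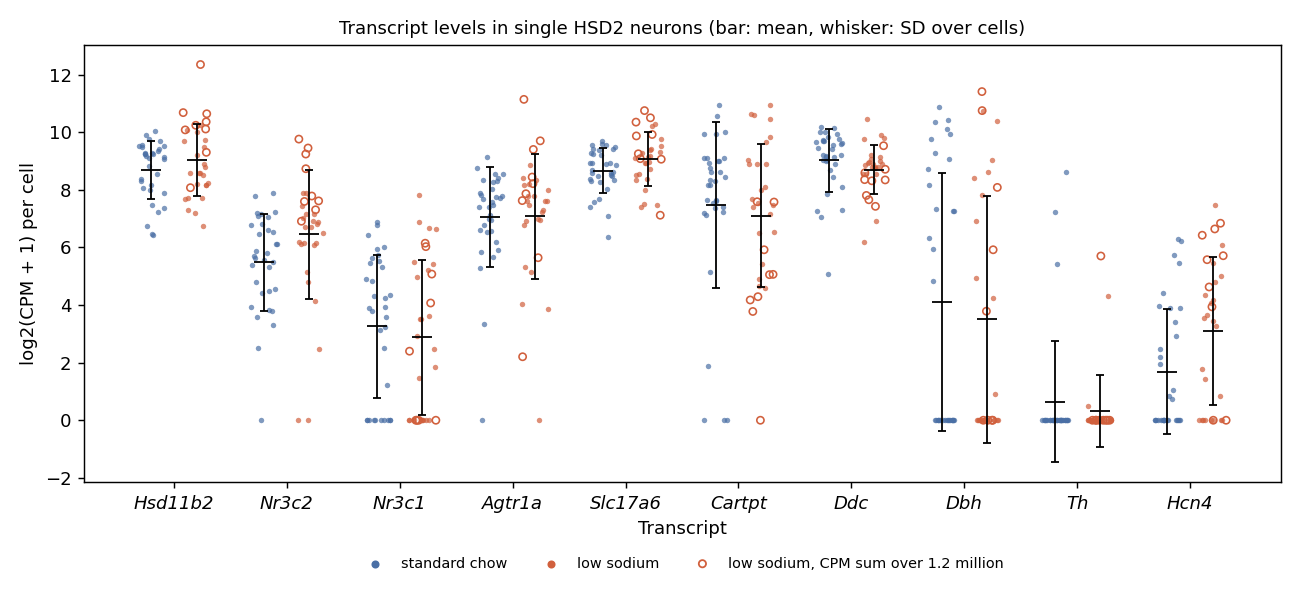
Each point is the log2(CPM + 1) of 1 transcript in 1 cell, for chow (33 cells) and low sodium (32 cells), with open points for the 9 cells with high CPM sums, bars for means and whiskers for the SD over cells. Hsd11b2, Slc17a6 and Ddc are above 0 in all 65 cells, whereas Dbh is at 0 in 34 cells and Th in all but 6.

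Among transmitter genes, Ddc, which encodes aromatic amino acid decarboxylase, was found in all 65 cells at 8.86 ± 0.98. Dbh, the enzyme that turns dopamine into noradrenaline, was found in 31 cells (47.7%, 35.1% to 60.5%) and the vesicular monoamine transporter gene Slc18a2 in 39 cells (60.0%, 47.1% to 72.0%). Th, which encodes the first enzyme of catecholamine synthesis, was found in 6 cells (9.23%, 3.46% to 19.0%), and in 2 of the 31 cells with Dbh (6.45%, 0.791% to 21.4%). The mean over the measured catecholamine markers was 2.60 ± 2.11 in chow and 2.21 ± 1.83 in low sodium, and that over Chat and Slc18a3, the cholinergic markers, was 1.23 ± 2.36 and 0.86 ± 1.71. Dbh was found in 16 of 33 chow and 15 of 32 low-sodium cells. The secretory granule genes Scg2 (9.70 ± 0.69), Cpe (9.60 ± 0.55), Pcsk1n (9.55 ± 0.94), Chgb (9.36 ± 0.82) and Chga (8.59 ± 0.91) were found in all 65 cells, and the neuropeptide gene Gal in 42 cells (64.6%, 51.8% to 76.1%).

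The neurons held transcripts of many channels that set firing. Of the sodium channel group, Scn9a (7.98 ± 1.07) and Scn2a1 (mean 7.52) were found in all 65 cells, Nalcn, a sodium leak channel, in 64 cells (7.00 ± 1.51), and Scn1a in 63 cells (6.95 ± 1.84). The abundant calcium channel genes were Cacna2d1 (7.19 ± 1.71, 64 cells), Cacna1b (6.48 ± 2.21, 61 cells), Cacna1e (6.01 ± 2.73, 60 cells) and Cacna1g, a T-type channel (5.78 ± 2.45, 60 cells). Potassium channel genes were led by Kcnip1 (7.67 ± 1.73) and Kcnc2 (7.65 ± 1.80). Of the HCN family, which carries pacemaker current, Hcn3 was found in 56 cells (5.05 ± 2.85), Hcn2 in 58 cells (4.25 ± 2.02) and Hcn4 in 38 cells (58.5%, 45.6% to 70.6%; 2.38 ± 2.46). Receptor genes found in all 65 cells included Chrnb2 (7.73 ± 1.65), a nicotinic receptor subunit, Gria2 (8.24 ± 0.94) and Gabbr1 (8.07 ± 0.93).

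The second question was how low-sodium cells differed from chow cells, given that the study concerns the state in which the neurons act as pacemakers. Genes of voltage-gated calcium channels had higher means in low sodium: 12 of 14 members were higher, with a median difference of 0.61 (percentile 99.99 among random lists). Cacna1c, an L-type channel, was 3.49 ± 2.38 in chow and 4.91 ± 2.66 in low sodium, a difference of 1.42 that was 0.86 without the 9 cells, and the auxiliary subunit gene Cacnb2 differed by 1.24 (1.05 without them). Cacna1d, the other L-type channel of neurons, named after its values were seen, was 4.71 ± 2.24 and 5.79 ± 2.62. Cacnb3, another auxiliary subunit gene, had the lower mean in low sodium (5.16 ± 2.35 and 3.73 ± 3.06), and Cacna1g differed by -0.44 (-1.14 without the 9 cells). Without the 9 cells with high CPM sums the median was 0.49 (percentile 99.95) and 10 of 14 members were higher. The median over the 10726 genes that enter the random lists was -0.12, so lists are read against random lists rather than against 0.

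Nuclear genes of oxidative phosphorylation, the subunits of the mitochondrial respiratory chain and ATP synthase, had lower means in low sodium. The median over 50 genes was -0.59 (percentile 0.00), and 48 of them were lower. Cox8a was 8.77 ± 0.85 in chow and 7.90 ± 1.16 in low sodium, Ndufc1 was 7.54 ± 0.65 and 6.67 ± 1.30, and Ndufa1 and Ndufs3 differed by -0.85 and -0.83. Without the 9 cells the median was -0.25 (percentile 0.08), again with 48 of 50 lower, and these 4 genes differed by -0.57, -0.23, -0.37 and -0.34. Genes of glycolysis had a median of -0.18 (percentile 22.7), and of -0.26 (percentile 5.22, 16 of 18 lower) without the 9 cells, with Pgk1 at -0.49, Ldhb at -0.57, Slc2a1 at -0.93 and Eno2 at 0.62 over all cells and at -0.38, -0.40, -1.27 and 0.03 without the 9. The mitochondrially encoded genes were not analysed here, since 0 of 13 listed genes were among those measured.

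Genes that corticosteroids are known to induce had lower means in low sodium: 11 of 14 were lower, with a median of -0.52 (percentile 1.66), and a median of -0.52 (percentile 0.84) without the 9 cells. The metallothionein genes Mt1 and Mt2 differed by -2.24 and -1.23, Errfi1 by -1.65 and Ndrg2 by -1.29. Without the 9 cells Mt1 differed by -1.57, Errfi1 by -2.14 and Ndrg2 by -1.15. Astrocytes also express Mt1, Mt2 and Ndrg2, and astrocyte markers were found in more chow cells: at least 3 exceeded 10 CPM in 10 of 33 chow cells (30.3%, 15.6% to 48.7%) and in 4 of 32 low-sodium cells (12.5%, 3.51% to 29.0%). The list was no longer apart without these 3 genes (-0.35, percentile 16.2), without the cells with non-neuronal markers (-0.42, percentile 18.3), after thinning (-0.57, percentile 5.76) or as the median over cells (-0.01, percentile 68.8).

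Genes of cholesterol synthesis had a median of -0.35 (percentile 4.41), with 18 of 22 lower, and a median of -0.40 (percentile 0.49), with 21 of 22 lower, without the 9 cells. Insig1, which holds back the pathway, was 6.10 ± 1.53 in chow and 4.91 ± 2.72 in low sodium. Hsd17b7 and Pmvk differed by -1.35 and -0.87 (-1.67 and -0.31 without the 9 cells). Among genes of the unfolded protein response in the endoplasmic reticulum, 15 of 19 were lower, with a median of -0.38 (percentile 1.94) that was -0.07 (percentile 54.8) without the 9 cells. Its member Ddit3, a stress-induced transcription factor, was 5.24 ± 1.93 and 2.90 ± 2.80, Creld2 and Pdia4 differed by -1.30 and -1.27, and the stress sensor gene Atf6 differed by 1.61 (-1.91, -1.11 and 1.15 without the 9 cells). Without the cells with non-neuronal markers, the medians were -0.33 (percentile 23.9) for cholesterol synthesis and -0.46 (percentile 4.97) for the unfolded protein response. Of the 9 cells, all but low-sodium neuron 45, which carried such markers, were kept there.

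Several groups of neuronal genes were apart only when the 9 cells with high CPM sums were kept (values in parentheses after those of single genes are without these cells). Voltage-gated sodium channels had a median of 0.34 (percentile 99.0) with these cells and -0.0033 (percentile 70.1) without them. Scn2a1 differed by 0.96 (0.52) and Scn2b by -1.08 (-0.45). Potassium channels had a median of 0.20 (percentile 99.7) and 0.03 (percentile 88.6) without the 9 cells, with Kcnc1 at 1.32 (1.07), Kcnd2 at -1.09 (-0.58), Kcnip3 at -1.31 (-1.27) and Kcnmb4 at -1.56 (-1.56). Sodium pump and ion transporter genes had 0.21 (percentile 98.0) and -0.14 (percentile 36.7), with Slc4a3 at 0.81 (0.36) and Atp1b2 at -0.80 (-2.07). Glutamate and GABA receptor genes had 0.24 (percentile 99.7) and -0.07 (percentile 61.6), with Gabre at 1.14 (0.34) and Gabbr2 at -0.98 (-1.23). Synaptic vesicle genes had 0.26 (percentile 99.1) and -0.14 (percentile 47.4), with Syn1 at 0.62 (-0.10). Ribosomal protein genes had -0.46 (percentile 0.00) and 0.0026 (percentile 83.5), with Rps25 at -1.12 (-0.45) and Rpl35a at -1.10 (-0.33). Against random lists matched on transcript length too, the ribosomal protein genes (percentile 9.50), sodium channels (88.6), the sodium pump list (79.0) and glutamate and GABA receptors (96.0) were not apart over all cells.

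**Figure D3:**
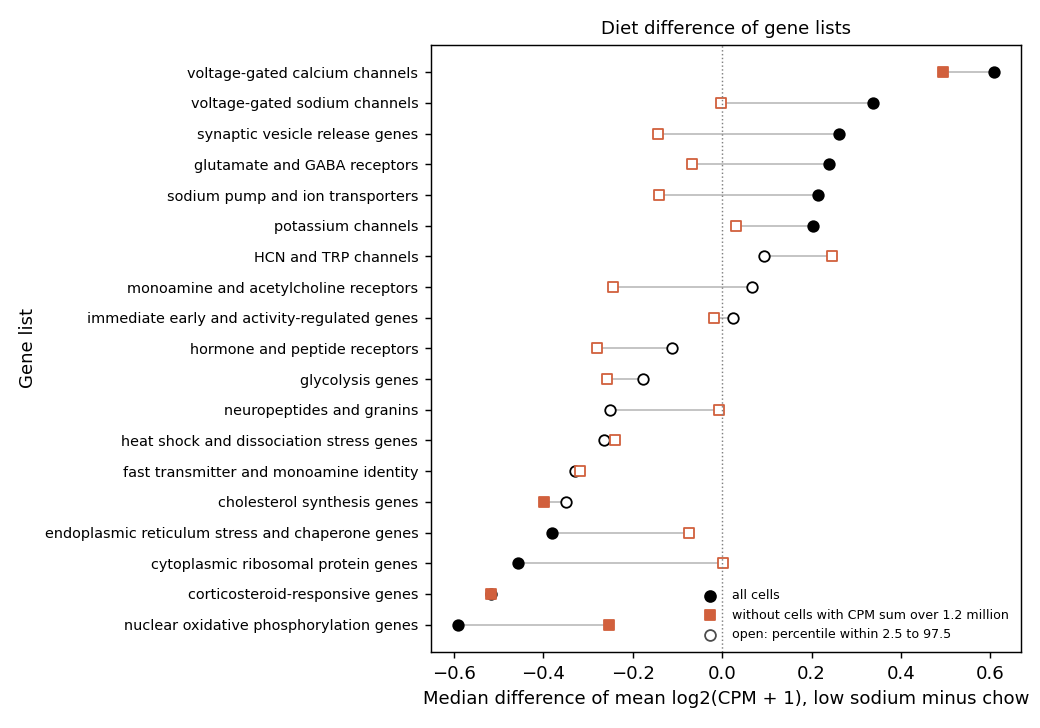
The horizontal axis is the median difference of mean log2(CPM + 1) over the members of each of 19 gene lists, low sodium minus chow, for all cells (circles) and without the 9 cells with high CPM sums (squares), with open symbols for lists that were not apart from random lists. Of 10 lists apart over all cells, 3 stay apart on the same side without the 9 cells.

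The remaining lists were not apart, with or without the 9 cells. Hyperpolarisation-activated and TRP channels had a median of 0.09 (percentile 83.6), and of 0.25 (percentile 96.0) without the 9 cells, with Hcn4 at means of 1.68 in chow and 3.10 in low sodium, a difference of 1.41 that was 0.90 without the 9 cells, Hcn3 at -0.96 and Trpm4 at -1.04. Immediate early genes, which neurons switch on with activity, had a median of 0.02 (percentile 81.0) and of -0.02 (percentile 73.1) without the 9, with Jun at 0.89, Fosb at 0.80, Ier2 at -0.82 and Vgf at -1.15 (-0.32 without the 9); without the cells with non-neuronal markers the median was 0.44 (percentile 99.9). Heat shock genes, which dissociation can induce, had a median of -0.26 (percentile 17.2) and of -0.24 (percentile 18.5) without the 9, with Hspa1a at 0.96 and Hspe1 at -0.53 (0.87 and 0.09 without the 9). Neuropeptide and granin genes had -0.25 (percentile 13.0) and -0.0074 (percentile 88.6) without the 9, with Nmb at -1.48, Gal at -0.85 and Nppa, the atrial natriuretic peptide gene, at 0.85 (-1.33, -0.42 and 1.06 without the 9). Hormone and peptide receptor genes had -0.11 (percentile 51.3) and -0.28 (percentile 16.0) without the 9, with Ramp1 at -1.45 and Sstr1 at -0.99. Monoamine and acetylcholine receptor genes had 0.07 (percentile 70.5) and -0.24 (percentile 30.0) without the 9, with Chrnb2 at 0.95 over all cells and -0.08 without the 9. Transmitter identity genes had -0.33 (percentile 19.5) and -0.32 (percentile 17.1) without the 9, with Dbh at -0.61, Slc18a3 at -0.41 and Ddc at -0.33 (-0.98, -0.75 and -0.17 without the 9). The identity panel had 0.03 (percentile 70.4) and -0.0065 (percentile 78.1) without the 9: Nr3c2 was 5.48 ± 1.69 in chow and 6.46 ± 2.23 in low sodium, a difference of 0.98 that was 0.27 without the 9 cells, while Agtr1a differed by 0.03 and Hsd11b2 by 0.35 (-0.25 and -0.10 without the 9).

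The 12 highest differences, in order, were those of Fbxl18 (2.33), Tunar (2.28), Rptor (2.22), Camsap3 (2.09), Nlgn1 (2.08), Sbf1 (2.06), Cd59a (2.04), Zfp180 (1.95), St6galnac5 (1.94), Ntng1 (1.92), Prrt2 (1.88) and Uhmk1 (1.87). Rptor, a part of the growth-regulating complex mTORC1, had means of 5.17 in chow and 7.39 in low sodium. Nlgn1, a synaptic adhesion gene, was 3.43 ± 2.61 and 5.51 ± 2.70, and Ntng1, an axon guidance gene, was 4.43 ± 2.33 and 6.35 ± 1.49. Without the 9 cells all 12 stayed above 0, at 0.75 or more, and 2 stayed among the 12 highest. Cd59a, Ntng1 and St6galnac5 were at 2.35, 1.83 and 1.92 without them, whereas Fbxl18, Camsap3 and Prrt2 were at 1.12, 1.18 and 0.75.

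The 12 lowest differences were those of Fam219b (-2.88), D17H6S53E (-2.43), Ddit3 (-2.34), Smim11 (-2.34), Dhrs3 (-2.33), Cdkn1b (-2.32), Apoe (-2.31), Vim (-2.28), Mt1 (-2.24), Plat (-2.23), Lxn (-2.21) and Nacc2 (-2.21). Of these 24 highest and lowest differences, 4 exceeded the SD over cells of both diets, those of Fam219b, D17H6S53E, Smim11 and Cdkn1b. Smim11 was 5.18 ± 1.02 in chow and 2.85 ± 2.14 in low sodium, and Cdkn1b, a cell cycle inhibitor, was 3.53 ± 1.83 and 1.22 ± 1.92. Apoe and Vim, which astrocytes express strongly, were 4.96 ± 3.95 and 2.65 ± 3.29, and 2.95 ± 3.38 and 0.66 ± 2.11. Without the 9 cells all 12 stayed below 0, at -1.57 or lower, and 5 stayed among the 12 lowest.

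Signals of other cell types were present in both diets. The astrocyte genes Slc1a3, Aqp4 and Gja1 had means of 3.11 ± 3.68, 2.03 ± 2.91 and 1.95 ± 2.99 in chow and 0.94 ± 2.35, 0.75 ± 1.92 and 0.64 ± 1.69 in low sodium. These were the largest differences of the astrocyte list, whose other 4 members with a mean of at least 1 differed by -0.57 to 0.03, and the list was not apart (percentile 6.10, and 27.1 without the 9 cells). Oligodendrocyte markers exceeded 10 CPM for at least 3 genes in 6 chow and 7 low-sodium cells, and the myelin gene Mbp was found in 54 of 65 cells. Ependymal and choroid plexus markers did so in 5 chow and 2 low-sodium cells, and endothelial markers in 2 and 1 cells. The mean over the 2 measured erythrocyte markers was 2.03 ± 1.46 and 2.72 ± 2.30. Markers of microglia were not analysed here. In total 14 chow and 10 low-sodium cells carried at least 3 markers of a non-neuronal list, and 4 of the 10 lists that were apart over all cells stayed so without them.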

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

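Leaving out the cells with high CPM sums, rescaling, matching on length and dropping Mt1, Mt2 and Ndrg2 were chosen after the values were seen. No paired analysis was possible because the numbers in the sample titles name single cells and no test was made. Calcium channel and oxidative phosphorylation genes kept their side of the random lists in all 15 settings that give a percentile, the corticosteroid list in 10 of 16. Of the 10 lists apart, 3 stayed so without the cells with high CPM sums, 4 without cells with non-neuronal markers, 6 when matched on length, 7 when thinned and 7 with the median over cells. The median over all genes was -0.27 after rescaling, -0.28 without the 20 highest genes, -0.05 with size factors and 0.16 as the log2 ratio of means, and all 10 lists stayed apart in each. Of 340 values of lists under alternatives, 334 stayed within the spread over cells with no change of sign in a called list. So did 1774 of 1780 values of named genes, with 6 beyond the spread as medians over cells. That spread is wide: it was 0.51 for synaptic vesicle genes, whose median over all cells was 0.26. Such a median could vanish and stay within the spread, so these counts say little about how firm a value is. Among lists that were apart, medians changed sign without the cells with high CPM sums in sodium channels (-0.0033), the sodium pump list (-0.14), glutamate and GABA receptors (-0.066), synaptic vesicle genes (-0.14) and ribosomal proteins (0.0026), and as the median over cells in the sodium pump list (-0.075); the cause was not tested. Thinning to 50000 reads, which removes reads by construction, gave Nr3c2 in 86.2% of cells, Nr3c1 in 46.2%, H6pd in 10.8%, Lmx1b in 9.23%, Agtr1a in 89.2%, Nr3c2 with Hsd11b2 in 86.2%, Nr3c2 with Agtr1a in 78.5%, Hsd11b2 with Agtr1a in 89.2%, Slc17a6 with an inhibitory marker in 16.9%, and medians of 6648 genes in chow and 6195.5 in low-sodium cells. Without the cells under 6473 genes, Nr3c2, Agtr1a and their pairs with each other and with Hsd11b2 were at 100%; the cause was not tested. A limit of 10 CPM, stricter by construction, gave Nr3c1 in 52.3%, Lmx1b in 12.3% and Slc17a6 with an inhibitory marker in 16.9%. At least 3 markers above 100 CPM were found in 7.69% of cells for astrocytes, 4.62% for oligodendrocytes and 1.54% for ependymal cells, and at least 2 above 10 CPM in 38.5% for oligodendrocytes and 24.6% for ependymal cells, limits that are stricter or looser by construction.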

Other observations

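The tests of a scaling factor, of the neuron numbers, of the list without the cells with high CPM sums, of the limits of the random lists, and of Slc18a2 in cells with Dbh were chosen after the result was seen. No prediction was written beforehand for Ddc in cells with neither Dbh nor Th. In the 9 low-sodium cells with high CPM sums, the mean log2(CPM + 1) of Hsd11b2 was 10.20, that of Nr3c2 8.27 and that of Cartpt 4.83. These levels are on the deposited scale, and with every cell rescaled to the same total they were 9.48, 7.55 and 4.19. The next genes named were chosen after their values were seen. Peg3, an imprinted zinc finger gene, was at 13.12 ± 0.35 in these cells and 10.16 ± 0.48 in chow cells, Ecel1, a neuronal peptidase, at 12.78 ± 0.66 and 9.85 ± 0.90, and Disp2 at 12.63 ± 0.38 and 9.59 ± 0.63. After rescaling these were 12.40 and 10.28, 12.06 and 9.98, and 11.91 and 9.72. The respiratory chain gene Ndufb4 was lower in them, at 1.89 ± 1.90 and 5.54 ± 0.64, as was Bdnf, a growth factor gene, at 1.43 ± 2.33 and 4.91 ± 2.55. The 9 cells are all low-sodium, so these comparisons with chow hold the diet too. Levels in the other low-sodium cells are not given here, except that Bdnf differed from chow by 0.46 without the 9 cells. Fos, an immediate early gene, was found in 53 of 65 cells, at 6.19 ± 4.05 in chow and 6.56 ± 3.28 in low sodium, a wide spread within each diet. The cells were picked from a papain suspension, so Fos made in the animal and Fos made during handling cannot be told apart.

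The profile of these 9 cells is the pattern a reader would most want to follow up. Over 3589 genes above 0 in at least 90% of cells, the SD of their difference from the other 23 low-sodium cells was 1.41, where the highest of 100 random picks of 9 of those 23 was 0.86. A single scaling factor per cell shifts all genes alike and would not widen this SD, so these values argue against it as the whole cause. The SD stayed above the picks after thinning to 50000 reads (1.84 and 1.04) and after removal of medians by transcript length and GC content over 3473 genes (1.22 and 0.799), which argues against each of these too as the whole cause, although the 10% of genes with the shortest transcripts had a median of -1.54 and the 10% with the longest 0.77 (Spearman 0.44 across genes, which are not independent). The 9 cells make up 9 of the 10 low-sodium cells with the highest numbers in the titles (42 to 57). Low-sodium neuron 52, inside that range, had a CPM sum of 987611, and 4 chow cells with numbers in that range had no high sum. A handling batch or a single animal may therefore be behind the profile, and these, and a biological state under low sodium, cannot be told apart with these labels.

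The lower means of corticosteroid-responsive genes in low-sodium cells stayed at percentile 0.84 without the 9 cells, which argues against those cells as the cause. The list was not apart without the cells with non-neuronal markers (percentile 18.26), without Mt1, Mt2 and Ndrg2 (percentile 16.17) or after thinning (percentile 5.76). The medians there were -0.42, -0.35 and -0.57 (SD over members 0.91, 0.63 and 0.90), against -0.52 (0.80) over all cells, while the lower limit of the random lists moved from -0.49 to -0.64, -0.54 and -0.66, so that a median of -0.52 would have lost its call in each. Such a loss decides nothing. A stricter criterion on the size of the median was tried after the values were seen and was not kept, and astrocyte RNA, depth and an effect of diet cannot be told apart with these values.

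Ddc was found in all 65 cells and Dbh in 31, whereas 29 of those 31 had no Th. Sequencing depth is argued against for Th at 10% of the Dbh level or more. In the median of the 29 cells, 3 reads of Th would have stood for 1.26% of the Dbh level. They would have stood for less than 10% in 21 of the 29. RNA lost before sequencing gives no reads at any depth, so these values do not bear on it. RNA from neighbouring catecholamine neurons would also bring Slc18a2, which was found in 61.3% of cells with Dbh (42.2% to 78.2%) and 58.8% of the 34 without it, which does not decide. In the 30 cells with neither Dbh nor Th, the median Ddc level was 462 CPM. There 3 reads stood for 0.878% of the Ddc level in the median cell and for at most 7.14%. These cells were selected for the absence of Dbh and Th, so the values speak for these 30 cells alone. Within them, the values argue against such neurons as the source of Ddc. This holds for neurons with Dbh or Th at 10% of their Ddc level or more, and leaves out RNA lost before sequencing. The levels of Th, Dbh and Ddc in such neurons were not measured, so for Dbh that source cannot be told apart from transcription in the cells themselves. A candidate explanation, as a hypothesis from these data alone, is that HSD2 neurons transcribe later enzymes of the pathway without the first, which was not tested by protein or by sequence.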
